A study of Homo sapiens with 6 samples.

How the data were processed

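ChIP-seq peak lists were analysed for SMARCE1 and SMARCC1 in HMLE-Twist-ER cells, untreated and after 14 days in 125 nM 4-OHT. The 6 samples of the series form 6 groups of 1 sample, taken from the sample titles and antibody labels. The 2 input DNA samples had no file used here, so 4 lists were analysed. Per the labels' protocols, sonicated chromatin was immunoprecipitated and made into TruSeq ChIP libraries. Per the submitters' processing notes, Bowtie 1.1.2 and MACS 1.0.0 were used with the build hg19; the role of each, the control, the threshold and the treatment of duplicate and multiply mapping reads are not given in the sources used here. Each deposited list has 5 columns: chromosome, start, end, peak name and a score that the authors' peak caller assigned to each peak. The lowest score in each list lies at 50.0 or just above. Scores are the authors' own values, may depend on depth, and were used to rank and describe peaks within a list. The alternative with a common score threshold filters all lists at 1 score, which need not be equally strict in each. Peaks were called per library, since each library has its own list. Peak lists hold no read numbers, so the depth behind a peak is unknown and a peak missing from a list is not evidence that the protein was absent.

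Number, covered length, width and score of peaks were computed per list. Lists were compared by overlap of at least 1 bp, and shares are given with exact Clopper-Pearson 95% intervals, which cover counting error only. Overlap was set against 1000 random placements with a fixed seed, each peak keeping its width and chromosome. Unassembled gaps were not excluded, since no hg19 sequence was used here. Random overlap is thus understated, and the fold excess over it overstated, by an amount that was not computed. This matters most where gaps fill much of a band. Ratios of densities have exact conditional intervals, densities have Poisson intervals, and ratios of medians were resampled 1000 times. All these intervals treat peaks as independent, so they are too narrow where peaks lie in groups. Chromosome lengths of hg19 came from the R package GenomeInfoDb 1.38.1 and cytogenetic bands from circlize 0.4.16; band ends equalled the chromosome lengths, and 0 peaks ran past a chromosome end. The centromere class holds peaks whose midpoint lies in, or within 5 Mb of, a centromeric or variable heterochromatin band. Groups of peaks were joined across gaps of up to 3 kb outside that class and compared with 100 placements within bands. The overlap code was tested on simulated lists of 2622 and 1239 peaks with 500 planted overlaps, and recovered 100% of them in both. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Coordinates count from 1.

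The overlap comparisons, their alternatives and the rule for named peaks were fixed before the data were examined. The rule names, where no matching annotation is used, the 3 highest-scoring peaks of each class by position (4-OHT only, both conditions, untreated only, and 4-OHT SMARCE1 peaks overlapping 4-OHT SMARCC1 peaks), with ties kept; shared peaks are ranked by the 4-OHT score. The centromere class, Giemsa bands, chromosomes, groups of peaks, placement within bands and chromosome ends were added after the data were seen. Promoter shares, 19 gene lists, 19 motifs and repeat filters had also been planned. They were not run, because they need an hg19 annotation or sequence and the gene table at hand is on GRCh38; no gene is therefore named at any peak. Alternatives tried were a common score threshold of 75.72 (the median over all lists), equal numbers of highest-scoring peaks, overlap of at least 50% of the shorter peak, a distance of 1 kb, leaving out peaks found in all 4 lists, and those added later: peaks outside the centromere class, autosomes only, autosomes and X, leaving out 8q21.2, margins of 1 and 10 Mb, and gaps of 1 and 10 kb.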

Results

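Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map SMARCE1 and SMARCC1, subunits of the SWI/SNF (BAF) chromatin remodelling complex, in HMLE-Twist-ER cells. These are immortalised human mammary epithelial cells that carry the transcription factor Twist fused to the ligand-binding domain of the estrogen receptor. The ligand 4-hydroxytamoxifen (4-OHT) activates the fusion, and the cells then undergo an epithelial to mesenchymal transition. Cells were left untreated or were kept in 125 nM 4-OHT for 14 days. The series holds 6 samples: SMARCE1 ChIP, SMARCC1 ChIP and input DNA in each of the 2 conditions, with 1 library per group. Peak lists of the 4 ChIP libraries were analysed, in hg19 coordinates. Read depth is unknown from these lists. With no replicates, differences between conditions describe these libraries and carry no p-value, and the 95% intervals below cover counting error only.

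The first comparison asked how much of the genome each list covered before and after induction. SMARCE1 peaks were 11.5-fold more numerous with 4-OHT, 30163 against 2622, whereas SMARCC1 peaks were 1.92-fold more numerous, 2375 against 1239. Covered length rose less than peak number for SMARCE1, from 670 kb to 3484 kb, a ratio of 5.20. For SMARCC1 it went from 339 kb to 541 kb, a ratio of 1.60. The added SMARCE1 peaks lay mostly on chromosome arms: outside a centromere class (peaks in, or within 5 Mb of, centromeric or variable heterochromatin bands) the ratio was 25.3, and inside it 2.72. The SMARCC1 ratio was 1.95 outside and 1.86 inside. Peaks were narrow in every list, with medians of 119 bp and 129 bp for untreated SMARCC1 and SMARCE1 and of 117 bp and 111 bp with 4-OHT. With 1 stricter score threshold for all lists, whose score scales may differ with depth, the SMARCE1 ratio was 19.97 and the SMARCC1 ratio 1.40. Most of the pooled peaks that set this threshold were 4-OHT SMARCE1 peaks. It kept 16791 of the 30163 4-OHT and 841 of the 2622 untreated SMARCE1 peaks, so it was not equally strict in both.

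Centromere-proximal DNA held a large part of 3 of the 4 lists. It held 61.1% of untreated SMARCE1 peaks (interval 59.2 to 62.97%), 35.4% of untreated SMARCC1 peaks (32.8 to 38.2%) and 34.4% of 4-OHT SMARCC1 peaks (32.5 to 36.4%), while the class makes up 15.4% of the hg19 length. With the common score threshold these 3 lists were closer to each other, with shares of 83.6%, 75.3% and 79.1%. Of 4-OHT SMARCE1 peaks 14.5% lay in the class (14.1 to 14.9%), close to its share of the hg19 length. Over autosomes and X the shares were 13.8% of peaks (13.4 to 14.2%) and 14.1% of the length. With margins of 1 and 10 Mb the class held 7.76% and 21.3% of peaks, against 9.29% and 22.4% of the length. These lengths include unassembled gaps, where no peak can be called. The bands 1q12 and 9q12, both in the class, held 1 and 3 of these peaks. The class's share of assembled sequence was not computed, so an excess of 4-OHT SMARCE1 peaks there is not excluded. The number of SMARCE1 peaks in the class still rose, from 1602 to 4365, but their covered length changed by a ratio of only 1.24. The band with the most untreated SMARCE1 peaks was 4p11, with 158, followed by 10q11.21 with 107 and 1p11.2 with 84. For untreated SMARCC1 the leading bands were 10q11.21, with 55 peaks, and 2p11.1, with 28. Among the 100 highest-scoring peaks of each list, 94 (untreated SMARCC1), 97 (untreated SMARCE1), 98 (4-OHT SMARCC1) and 88 (4-OHT SMARCE1) were in the class. The class was defined after the data were seen. No input peak list was analysed here, so the level at these repeats without an antibody is not known.

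**Figure D1:**
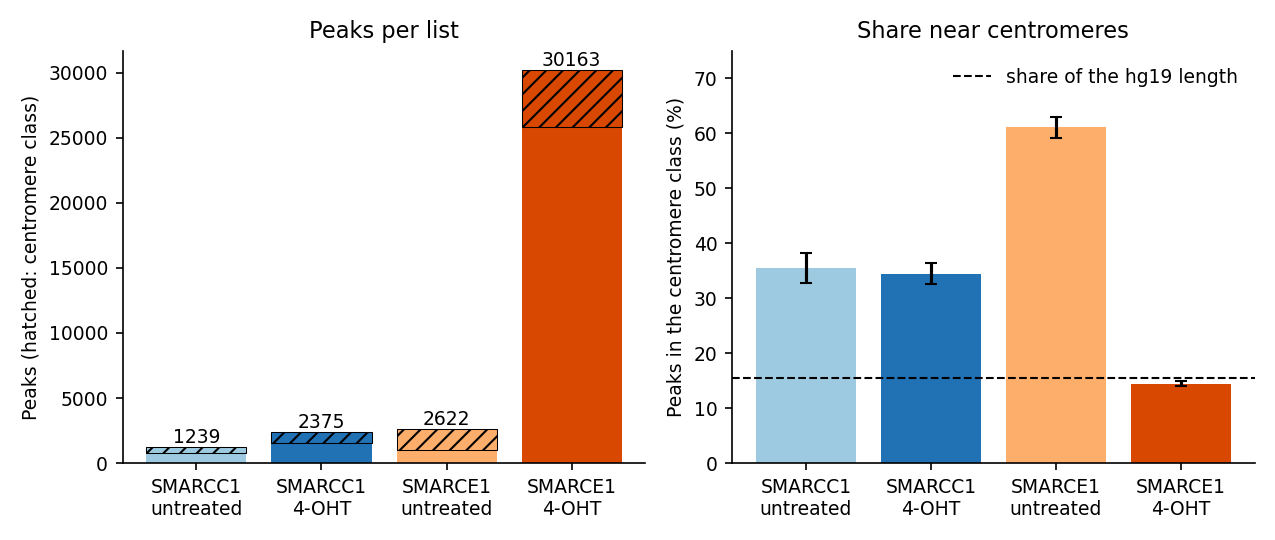
The left panel plots the number of peaks per list, with the centromere class hatched. The right panel plots the share of peaks in that class in percent, with exact 95% intervals as error bars and its share of the hg19 length as a dashed line; untreated SMARCE1 was highest at 61.1% and 4-OHT SMARCE1 lowest at 14.5%.

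The second comparison asked whether SMARCE1 was found at the same places in both conditions. Of the 2622 untreated peaks, 832 (31.7%, interval 30.0 to 33.6%) overlapped a 4-OHT SMARCE1 peak by at least 1 bp, and 3.51% of 4-OHT peaks overlapped an untreated one. The greater length of the 4-OHT list limits the latter share. It was 17.0% with equal numbers of highest-scoring peaks and 0.496% outside the centromere class. The shared sites were mainly pericentromeric: 44.2% of untreated peaks in the centromere class recurred with 4-OHT, against 12.2% of those outside (124 of 1020 peaks, 10.2 to 14.3%). The highest shared peaks, tied at the authors' score of 3100 in the 4-OHT list, were in 1p11.2 (chromosome 1, 121484053 to 121485434), 10q11.21 (chromosome 10, 42384904 to 42385729), 2p11.1 (chromosome 2, 92317492 to 92319592), Xp11.1 (chromosome X, 58566531 to 58574406) and, at the first assembled bases of 5p15.33, chromosome 5, 10001 to 11797. Of the highest peaks found only with 4-OHT, those in 12q14.3 (chromosome 12, 66451345 to 66451462, score 778) and 15q24.3 (chromosome 15, 77910868 to 77910953, score 684) lay on chromosome arms. Another was in 16q11.2 (chromosome 16, 46388161 to 46395052, score 766), a heterochromatin band, and overlapped an untreated SMARCC1 peak. The highest peaks found only untreated were in 21p11.2 (chromosome 21, 9825438 to 9827583, score 804), 10q26.3 (chromosome 10, 135499878 to 135501443, score 367) and 16p11.2 (chromosome 16, 33963036 to 33963499, score 290). The first 2 overlapped peaks of both SMARCC1 lists, and the third a 4-OHT SMARCC1 peak. In 1000 random placements of the untreated peaks on their own chromosomes, a mean of 9.14 overlapped and the highest number was 20. The observed overlap was 91.1-fold above that mean, or 31.0-fold when peaks were placed within their own cytogenetic band. Among the 2622 highest-scoring peaks of both lists the overlap was 12.8%, and it was 50.3% with the common score threshold and also 50.3% when peaks within 1 kb counted as shared.

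The same question was asked of SMARCC1. Of 1239 untreated peaks, 257 (20.7%, interval 18.5 to 23.1%) overlapped a 4-OHT SMARCC1 peak, against a random mean of 0.48 on the chromosome and 3.40 within bands. With the common score threshold the share was 59.8%. Almost all of them were near centromeres: 239 of 439 peaks in the centromere class recurred (54.4%), and 18 of 800 outside it (2.25%, 1.34 to 3.53%). The highest peaks found in both conditions were in 16q11.2 (chromosome 16, 46396918 to 46403964), 2p11.1 (chromosome 2, 92305938 to 92309386) and 8q11.1 (chromosome 8, 46851913 to 46856453). The 3 highest found only with 4-OHT were in Xq11.1 (chromosome X, 61698865 to 61702615, 61703527 to 61705923 and 61692493 to 61694821). The 3 highest found only untreated were in 2p11.1 (chromosome 2, 92315721 to 92324025 and 92324310 to 92326171) and Xp11.1 (chromosome X, 58566359 to 58574664). All 6 of these condition-specific SMARCC1 peaks overlapped peaks in 2 of the 3 other lists.

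The third comparison asked how far the subunits occupied the same sites within a condition. In untreated cells 348 of 1239 SMARCC1 peaks (28.1%, interval 25.6 to 30.7%) overlapped a SMARCE1 peak, against a random mean of 0.577 on the chromosome and 5.36 within bands; with the common score threshold the share was 76.2%. Near centromeres the share was 74.3% (69.9 to 78.3%), and outside it was 2.75% (22 of 800 peaks, 1.73 to 4.13%). With 4-OHT 444 of 2375 SMARCC1 peaks (18.7%, 17.1 to 20.3%) overlapped a SMARCE1 peak, although the SMARCE1 list was then 11.5-fold longer. The share was 44.7% near centromeres and 5.01% outside (78 of 1557 peaks, 3.98 to 6.21%). Outside the class this was 24.2-fold above the random mean of 3.22 peaks and 17.1-fold above that within bands, 4.56 peaks. Over all peaks the share was 61.8% with the common score threshold, 9.68% with equal numbers of highest-scoring peaks and 29.9% within 1 kb. In the other direction, 2.17% of 4-OHT SMARCE1 peaks overlapped a 4-OHT SMARCC1 peak, and outside the centromere class 0.318%, or 82 of 25798 peaks. With equal numbers of highest-scoring peaks this share was 14.1% over all peaks. The highest 4-OHT SMARCE1 peaks that overlapped SMARCC1 were those named above in 1p11.2 and 10q11.21 and another in 10q11.21 (chromosome 10, 42599489 to 42600543, score 2573). Outside the centromere class the highest were in 2q12.3 (chromosome 2, 109815790 to 109816309), 3q29 (chromosome 3, 196625623 to 196625779) and 12p13.32 (chromosome 12, 4093266 to 4093332). Sites present in all 4 lists were rarer still on chromosome arms: 227 untreated SMARCC1 peaks met this, and 221 of them (97.4%, 94.3 to 99.0%) were in the centromere class.

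**Figure D2:**
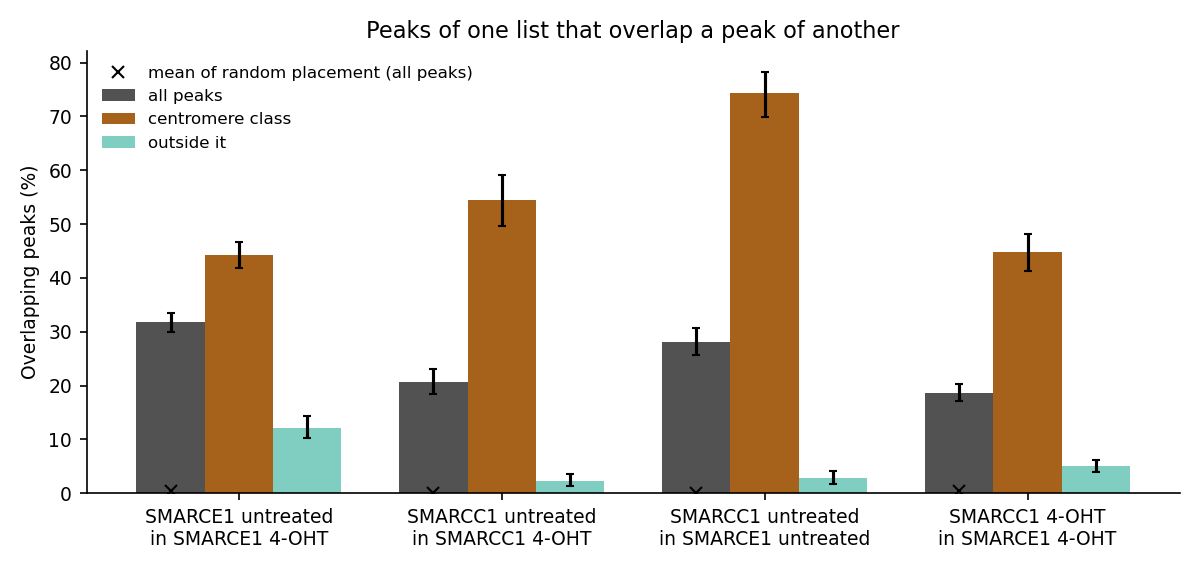
The vertical axis gives the percent of the peaks of the first list that overlap a peak of the second, for all peaks and by region, with exact 95% intervals; crosses give the mean of random placement. In each of the 4 comparisons the share was higher in the centromere class, from 44.2% to 74.3%, than outside it, from 2.25% to 12.2%.

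Peaks shared between conditions were wider and had higher authors' scores than unshared peaks of the same list. Shared untreated SMARCC1 peaks had a median width of 427 bp (quartiles 250 and 828) against 114 bp (101 and 127) for unshared ones, and shared 4-OHT SMARCC1 peaks had 512 bp against 115 bp. The SMARCE1 difference was smaller, 241 bp against 121 bp untreated and 163 bp against 111 bp with 4-OHT. Median scores of shared and unshared peaks were 94.8 and 58.3 for untreated SMARCC1, 122 and 55.5 for 4-OHT SMARCC1, 90.5 and 61.3 for untreated SMARCE1, and 103 and 76.9 for 4-OHT SMARCE1. Outside the centromere class the score differences were smaller: the ratio of shared to unshared medians fell from 2.19 to 1.27 for 4-OHT SMARCC1 and was 1.32 for untreated SMARCC1 and 1.08 for SMARCE1 in both conditions. There, the width of shared and unshared peaks was close for SMARCE1, 125 and 119 bp untreated and 116 and 111 bp with 4-OHT. For SMARCC1 the difference stayed there, 342 and 114 bp untreated and 340.5 and 112 bp with 4-OHT, on 18 shared peaks in each list.

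Away from centromeres, SMARCE1 peaks with 4-OHT were distributed differently from those of the other lists. Giemsa-light bands are gene-rich and the darkest bands are gene-poor and AT-rich. The density of 4-OHT SMARCE1 peaks was 9.04 per Mb in light bands and 11.4 per Mb in the darkest, a ratio of 1.26 (interval 1.22 to 1.30). The same ratio was 0.712 (0.586 to 0.860) for untreated SMARCE1, 0.619 (0.493 to 0.770) for untreated SMARCC1 and 0.641 (0.545 to 0.750) for 4-OHT SMARCC1, so that their peaks were denser in light than in the darkest bands. The light band 8q21.2 alone held 57 of the 477 untreated SMARCE1 peaks in light bands, and no ratio was computed without it. In these 3 lists the palest dark bands had the highest density of the 5 stains, 0.592, 0.361 and 0.717 per Mb. By chromosome, 4-OHT SMARCE1 peaks were densest on X, at 13.7 per Mb, and on chromosome 4, at 11.5 per Mb. They were sparsest on chromosomes 21 and 22, at 4.96 and 4.999 per Mb. These divisions were chosen after the data were seen.

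**Figure D3:**
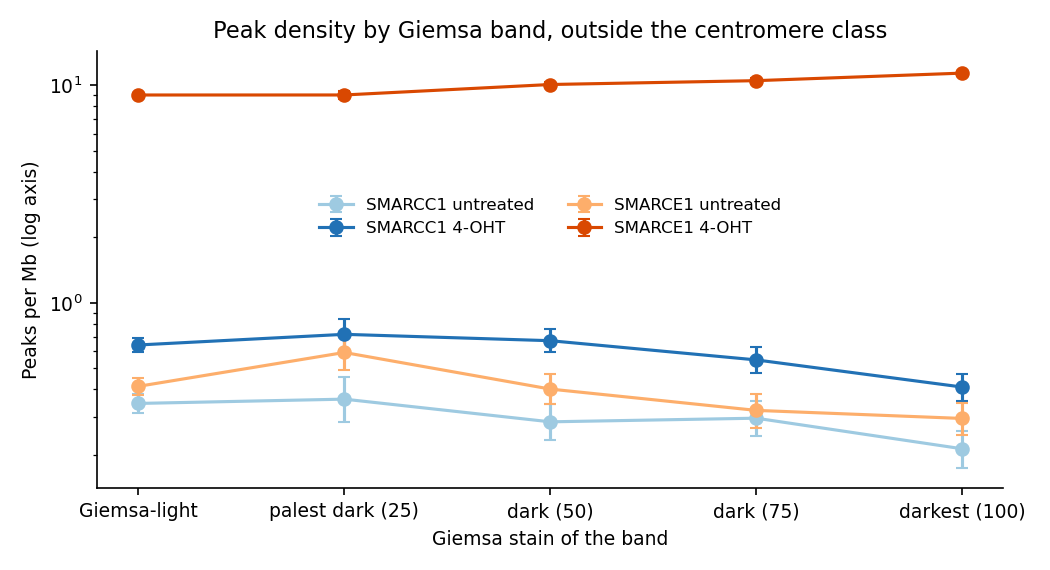
Peaks per Mb, on a log axis, are plotted by the Giemsa stain of the band for each list outside the centromere class, with 95% Poisson intervals as error bars. The density of 4-OHT SMARCE1 peaks rises from 9.04 in light bands to 11.4 in the darkest, and in the 3 other lists it is lower in the darkest bands than in light ones.

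Peaks of every list lay in groups more often than under random placement within bands, and the share of grouped peaks was highest for 4-OHT SMARCE1. Outside the centromere class 51.3% of its peaks (interval 50.7 to 51.9%) had another peak within 3 kb, against 6.73% at random, 7.62-fold more. The share was 14.3% for untreated SMARCE1 (1.41% at random), 4.38% for untreated SMARCC1 (0.263%) and 5.84% for 4-OHT SMARCC1 (0.753%), so that the excess over random was 10.2, 16.7 and 7.76-fold in these shorter lists. There were 2117 groups of 3 or more 4-OHT SMARCE1 peaks, holding 8468 peaks, with a median span of 2.75 kb. Apart from groups in 8q21.2, described below, those with the most peaks were in the Giemsa-light band 19q13.33 (chromosome 19, 50594977 to 50610300, 19 peaks over 15.3 kb), and in 3q26.1 (chromosome 3, 162954734 to 162959484) and 5q33.2 (chromosome 5, 155489724 to 155498981), which are dark bands, with 11 peaks each over 4.75 and 9.26 kb. An untreated SMARCE1 peak was found in 3.07% of these groups and a 4-OHT SMARCC1 peak in 3.02%. Single peaks of these groups overlapped 4-OHT SMARCC1 peaks in 0.543% of cases, against 0.208% of the other 4-OHT SMARCE1 peaks outside the centromere class. Without 8q21.2 these shares were 0.395% and 0.202%. For untreated SMARCE1 peaks the direction depended on that band, with 0.579% against 0.456% with it and 0.383% against 0.451% without it. The examples were chosen after their values were seen.

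**Figure D4:**
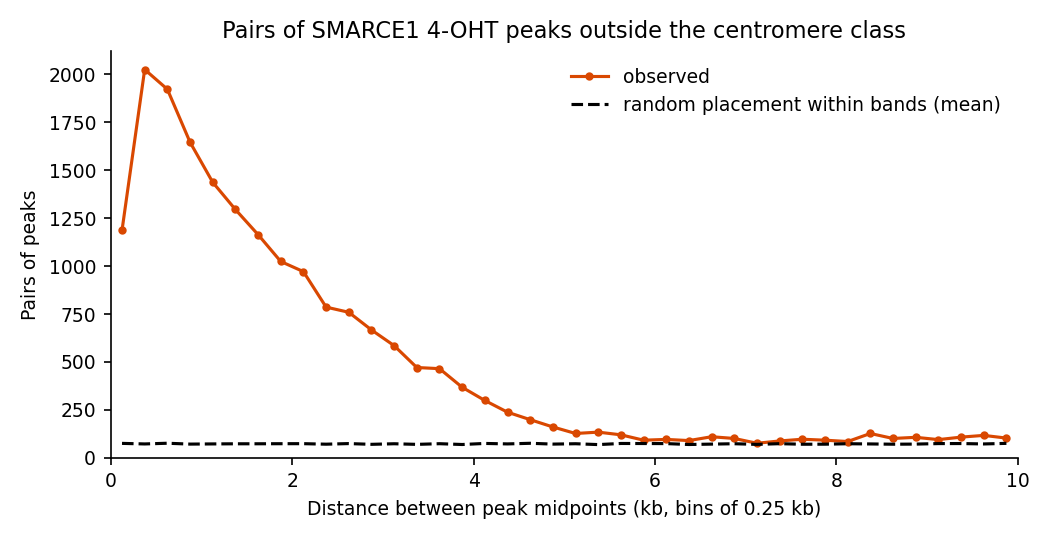
The number of pairs of 4-OHT SMARCE1 peaks outside the centromere class is plotted against the distance between their midpoints in kb, with the mean of 20 random placements within bands as a dashed line. There were 1922 pairs in the bin from 500 to 750 bp, where random placement gave 76.1, and the excess fell from 19.9-fold between 0 and 2 kb to 1.30-fold between 6 and 8 kb and 1.44-fold between 8 and 10 kb, without ending in the range plotted.

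A region of 8q21.2, far from the centromere, held dense groups of peaks in 3 lists. Between 86.5 and 86.9 Mb of chromosome 8 there were 56 untreated SMARCE1 peaks, 39 4-OHT SMARCC1 peaks and 98 4-OHT SMARCE1 peaks, but 2 untreated SMARCC1 peaks. A group of 24 4-OHT SMARCE1 peaks from 86759892 to 86776177 had the most peaks of any group outside the centromere class. The spacing of 4-OHT SMARCE1 peaks recurred within the region. Peaks starting at 86767342, 86767514, 86767973 and 86768155 were spaced like those starting at 86794815, 86794987, 86795446 and 86795628. Copies of a repeated sequence could give this, so the peaks may not be separate sites. The sequence under them was not used. This region was chosen after its values were seen.

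**Figure D5:**
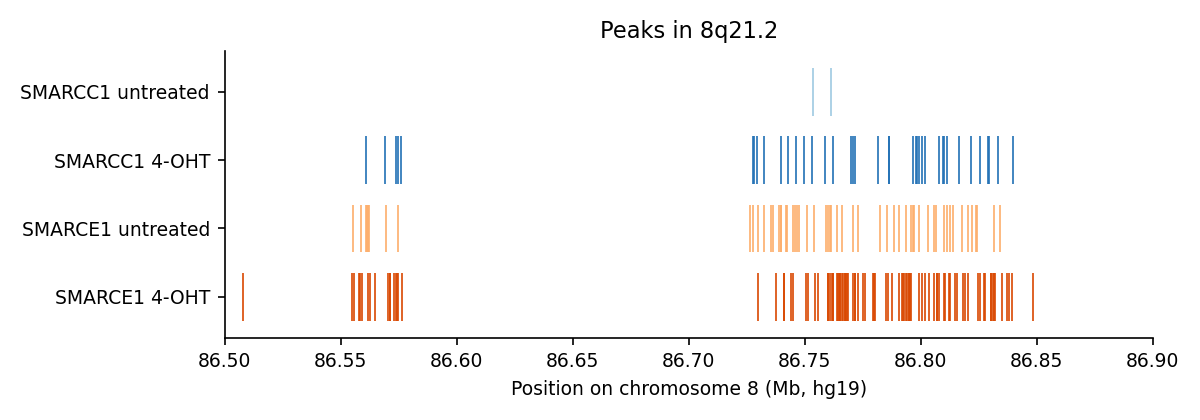
Each vertical line marks the start of a peak on chromosome 8 (hg19, in Mb) in each of the 4 lists. The window from 86.5 to 86.9 Mb holds 98 4-OHT SMARCE1 peaks and 2 untreated SMARCC1 peaks.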

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

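With 1 library per group, these alternatives show how values move with processing and not how they would vary between cultures; read depth, which limits every peak number, is unknown, and the cause of each change below was not tested. Lists are given in the order untreated SMARCC1, untreated SMARCE1, 4-OHT SMARCC1, 4-OHT SMARCE1. No paired analysis was possible because each group has 1 sample and the results come from no test. Repeat filters, placement by distance to promoters, and all promoter, gene-list and motif alternatives were not run. The restriction to peaks outside the centromere class, autosomes only, autosomes and X, placement within bands, margins and gaps were chosen after seeing the data. An alternative value was counted as moved when it left the 95% interval of the value reported or, for peak numbers and covered lengths, differed from it by over 1.5 times. By this rule 26 stayed and 66 moved, 49 of them lower and 17 higher. Peak numbers and covered lengths are part of this tally and could only fall, since each of their alternatives leaves peaks out. For the share of the other list that overlapped, 8 stayed, 6 were lower and 10 higher. The order of peak numbers between conditions was the same under each alternative. At a score of at least 75.72, peak numbers were 239, 841, 335 and 16791 and covered lengths 191, 416, 259 and 2001 kb. Outside the centromere class the first 3 lists held 800, 1020 and 1557 peaks over 106, 151 and 204 kb. Without peaks found in all 4 lists, the SMARCC1 lists covered 181 and 357 kb. The share in the centromere class was 29.8%, 53.01%, 27.1% and 7.76% with a 1 Mb margin and 39.8%, 65.7%, 40.0% and 21.3% with 10 Mb; over autosomes and X it was 58.8% for untreated and 13.8% for 4-OHT SMARCE1; with the score threshold it was 75.3%, 83.6% and 79.1% in the first 3 lists. Untreated SMARCE1 peaks overlapped 4-OHT peaks in 50.3% with the score threshold, 12.8% with equal numbers, 50.3% within 1 kb and 12.2% outside the centromere class. For SMARCC1 the overlap between conditions was 59.8% with the threshold, 24.1% within 1 kb and 2.25% outside the class. SMARCC1 overlapped SMARCE1 untreated in 76.2% with the threshold and 2.75% outside the class. With 4-OHT it did so in 61.8% with the threshold, 9.68% with equal numbers, 29.9% within 1 kb, 5.01% outside the class and 16.8% on autosomes. In that order of comparisons, overlap was 31.0, 75.5, 64.9 and 26.6-fold above placement within bands and 55.3, 142, 275 and 24.2-fold above placement outside the class, or 31.8, 103, 153 and 17.1-fold above placement within bands outside the class. Counting peaks within 1 kb as shared gave ratios of shared to unshared medians of 1.22 (score) and 1.55 (width) for untreated SMARCE1, 1.11 and 1.17 for 4-OHT SMARCE1 and 1.79 (score) for 4-OHT SMARCC1. Peaks in groups made up 10.1%, 4.43% and 37.6% of the last 3 lists with 1 kb gaps and 17.5%, 8.73% and 57.5% with 10 kb gaps. The excess of grouped peaks over random in the 4 lists was 50, 17.0, 15.4 and 15.3-fold with 1 kb gaps. With 10 kb gaps it was 6.96, 4.62, 4.23 and 2.88-fold.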

Other observations

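SMARCE1 peaks were also found at the ends of chromosomes. Within 20 kb of an end lay 9 untreated SMARCE1 peaks at 8 ends, against a mean of 0.846 and a highest number of 4 in 1000 random placements. All 8 ends also held a 4-OHT SMARCE1 peak. That list had 17 such peaks, against a mean of 8.70 and a highest number of 18 at random. Random peaks could also land in unassembled bases at the ends, where no peak can be called. Random numbers here are thus overstated, and the 17 peaks cannot be called a chance number. SMARCC1 had 1 such peak in each condition. The untreated one, in 9p24.3 (10233 to 10339), overlapped a peak of each SMARCE1 list. The SMARCE1 peaks began at the first assembled bases of 1p36.33 (10002 untreated), 5p15.33 (10002), 7p22.3 (10004), 4p16.3 (10008) and 18p11.32 (10021). Repeats that the assembly holds in too few copies may gather reads there in any library, which was not tested. At 17p13.3 5 peaks between 16517 and 18495 were in the 4-OHT SMARCE1 list alone. These sites and all tests below were chosen after the data were seen.

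The rise in SMARCE1 peak number with 4-OHT was set against technical explanations of depth and of the untreated list, and none is excluded. False or non-specific calls in the 4-OHT SMARCE1 list itself were not tested and stay open. Outside the centromere class 82 of its 25798 peaks (0.318%) overlapped a 4-OHT SMARCC1 peak, against a random mean of 3.40. The SMARCC1 list held only 1557 peaks there, which limits this share, so it does not tell false calls from true ones. If the 4-OHT library were only deeper, with sites that include those of the untreated list, strong untreated sites should recur. In the centromere class 85.6% of untreated peaks with scores of 100 or more did (interval 81.9 to 88.8%), and outside it 39.2% (20 of 51 peaks, 25.8 to 53.9%). Of the 255 highest-scoring peaks outside, which start near the floor of the list at a score of 68, 22.0% did (17.0 to 27.5%). Most strong untreated peaks outside the class thus did not recur. The test was first drafted on these 255 peaks and moved to scores of 100 or more after the overall overlap had been seen. Its limit for excluding the explanation was also set after the data were seen. The interval of the 51 peaks reached past that limit and that of the 255 did not, so the explanation stays open. An untreated library too shallow to show the 4-OHT sites, with false calls in its list, cannot be told apart from sites lost and gained on induction: 83.5% of the untreated peaks outside the class (81.1 to 85.8%) were in no other list, and either would give that. A biological response to induction of Twist remains open and untested without replicates.

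Peaks shared by all lists lay near centromeres whatever the antibody or treatment, 97.4% of them for untreated SMARCC1. Satellite repeats that the assembly holds in too few copies may gather reads there in any library. Occupancy of pericentromeric chromatin by the complex would give the same value, so these cannot be told apart without peaks or reads from input, which were not used here. Every list also held peaks on chromosome Y. Leaving Y out lowered the share in the centromere class in each, for untreated SMARCE1 from 61.1% to 58.8%. Whether these cells carry a chromosome Y was not examined. If they do not, such peaks come from misplaced reads.

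The groups of SMARCE1 peaks with 4-OHT exceeded chance: 8468 peaks lay in groups of 3 or more, against at most 171 in 100 placements within bands. Gene-rich regulatory regions as the only setting would make groups at least as dense in light as in the darkest Giemsa bands. Groups were denser in the darkest bands by a ratio of 1.39 (interval 1.24 to 1.55). All peaks of the list were too, with no detectable excess of groups per peak (ratio 1.101, 0.982 to 1.23), so the ratio restates where the list's peaks lay. The stain of a band does not show whether a group lies near genes, so this setting stays open. Light bands held 827 of the 2117 groups. Full-length L1 elements, retrotransposons common in dark bands and on chromosome X, are a hypothesis that these data leave open. Of groups joined across gaps of up to 10 kb, 12.8% spanned over 7 kb, and of those joined across up to 3 kb, 0.709%. X had no detectable excess of groups per peak over the autosomes (ratio 0.982, interval 0.829 to 1.16). Sequence that drew both grouped and single peaks to X would leave this ratio unchanged, so it cannot count against L1. Per Mb, X had 1.11 groups against an autosomal median of 0.769. Chromosome 4 had 1.13 groups per Mb, so X was not the highest. Other AT-rich sequence cannot be told apart from L1 here, since the sequence under the peaks was not used.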
